A study of Homo sapiens with 6 samples.

How the data were processed

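Bulk RNA sequencing of HEC-1B cells, a human endometrioid carcinoma line, was analysed in 6 libraries that fall into 3 groups of 2. Per the labels' protocols, total RNA was extracted with a miRNeasy kit, cDNA was made with the SMART-Seq v4 kit, and libraries were prepared with a Nextera kit. The authors deposited 1 table per library with 1 FPKM value (fragments per kilobase of transcript, scaled to the number of mapped fragments) per gene symbol, in the same genes for each library. Per the submitters' processing notes, the tools were TopHat2 2.0.13 and Cuffnorm 2.2.1 and the genome build was hg19; the annotation and the way Cuffnorm scaled the libraries are not given in the sources used here. The kit does not record the strand, so overlapping and antisense genes cannot be separated.

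FPKM values are not counts, so no count model was used. Depth was recovered in part from low values: genes under 0.3 FPKM whose values in a pair of libraries share the same ratio, within 3%, carry the ratio of what 1 fragment is worth. Relative to replicate 1 of the high-potential accelerated group, depth was 0.807 in its replicate 2, 0.93 and 0.909 in the parental accelerated libraries and 1.07 and 0.935 in the high-to-low libraries. At the estimated FPKM denominators, 1 fragment on a transcript of 1 kilobase is worth 0.0906 to 0.121 FPKM. Of the listed symbols, 22023 matched a RefSeq gene type, and 1615 were small RNA genes, which held between 9.06 and 18.73% of the summed FPKM. The reference at hand is of another build (GRCh38), so it was used for gene types, GC content, transcript length and the order of neighbouring genes, and no coordinates are printed. No symbol occurred more than once, so the planned choice between rows of the same symbol changed nothing.

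Genes with at least 1 FPKM in at least 2 libraries were kept, which left 12135. Values were transformed to log2(FPKM + 1), and 1 limma model (limma 3.58.1 in R 4.3.3) with a variance trend was fitted over all 6 libraries with 3 residual degrees of freedom. A fold change is therefore on the log2(FPKM + 1) scale, which understates changes of low genes. There were 4 comparisons: the mean of the accelerated groups against high-to-low, each accelerated group against high-to-low, and the accelerated groups against each other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. For ALDH1A1 and GPM6B an exact permutation test was run as well. No source states whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

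The genes named for a comparison are the 12 with the greatest positive and the 12 with the most negative log2 fold change among called genes whose libraries do not overlap between the sides and whose higher side has a mean of at least 3 FPKM. Where fewer passed, genes with an unadjusted p under 0.05 filled the places and are said not to pass. ALDH1A1, the sorted marker, and GPM6B are given in each comparison, and members of gene lists serve as examples. GPM6B was included because it is recalled as a gene of interest from the literature on these cells. Fixed gene lists (32, of which 28 had at least 3 kept members) were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation. These choices and 19 alternative settings were fixed before the data were examined. The alternatives changed the pseudocount, the filter, the scaling, the variance model, the libraries in the fit, the batch and block terms and each replicate in turn. Leaving out small RNA genes, and the overlap of the genes of lowest p in simulated unchanged groups, were added after the data were seen.

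The gene and list steps were tested on simulated data for the comparison between the accelerated groups, with 12135 genes and 200 changed genes in each of 5 sets. The limma step recovered 11% of genes changed by 1 on the log2 scale, 63% at 2 and 92.1% at 4, and 22 of its 584 calls fell on unchanged genes. A simulated shift of 1 in the cell cycle list (30 genes) was called in 5 of 5 sets at the preset correlation and in 3 of 5 with an estimated correlation. In these runs 1 call in total fell on another list. Smaller shifts and other lists were not simulated, so the test says nothing of calls with smaller medians.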

Results

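Gene expression was measured in HEC-1B cells sorted by aldehyde dehydrogenase (ALDH) activity, a property used to mark stem-like cancer cells. The series asks how expression differs between cultures with and without an accelerated passage from the ALDH1A1-low to the ALDH1A1-high state. The first group of 2 libraries came from HEC-1B cells labelled as having high ALDH potential, with accelerated transition (high-potential accelerated). The second came from HEC-1B cells without that label, also accelerated (parental accelerated), and the third from such cells labelled high to low (high-to-low). In each library 14786 to 15386 genes had a value above 0 and 11392 to 11726 reached 1 FPKM. Relative depth, with high-potential replicate 1 at 1, was 0.807 in the shallowest library and 1.07 in the deepest, and 1 fragment on a transcript of 1 kilobase was worth 0.0906 to 0.121 FPKM. Pearson correlations of log2(FPKM + 1) across kept genes were 0.943 between the high-potential libraries, 0.932 between the parental accelerated libraries and 0.947 between the high-to-low libraries. The highest, 0.964, was between parental accelerated replicate 1 and high-to-low replicate 1. Correlations of high-potential with other libraries lay between 0.897 and 0.926; genes are not independent replicates in these values.

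ALDH1A1, which encodes a retinaldehyde dehydrogenase and is the marker behind the sort, stood at 352.5 and 303.6 FPKM in the high-potential accelerated libraries (328.1 ± 34.6, SD, n = 2). It was 28.4 and 9.45 FPKM in the high-to-low libraries (18.9 ± 13.4, SD, n = 2). The parental accelerated libraries lay far apart: ALDH1A1 was 26.7 FPKM in replicate 1, inside the high-to-low range, and 316.9 in replicate 2. Over the 4 accelerated libraries against high-to-low the log2 difference was 3.33 (SE 0.946, limma adjusted p = 0.462), and the exact permutation test gave p = 0.133, where the smallest possible is 0.0667. Against high-to-low, the high-potential libraries were higher by 4.23 (SE 1.09, limma adjusted p = 0.127) and the parental accelerated libraries by 2.42 (SE 1.09, limma adjusted p = 1). The accelerated groups differed by 1.81 (limma adjusted p = 0.527). None of these passed the threshold, and 2 libraries against 2 cannot give an exact p below 0.333. With the parental accelerated libraries out of the fit, the difference of 4.23 had a limma adjusted p of 0.0362, within a range of 0.0362 to 0.447 over the alternatives. Without parental accelerated replicate 1 the difference between the accelerated groups was 0.05, and without replicate 2 it was 3.57.

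GPM6B, which encodes the neuronal membrane glycoprotein M6-b, was low in every library. It was 0.449 and 0.294 FPKM in the high-potential, 0.537 and 0.439 in the parental accelerated and 0.177 and 0.139 in the high-to-low libraries. It was higher in 4 of 4 accelerated libraries than in either high-to-low library, and the two-sided exact permutation p of 0.0667 is the smallest that 4 against 2 libraries allow. The gene was recalled from literature that may rest on these same libraries, so that p may not be an independent test. GPM6B fell below the filter on low values; in the fit without a filter the log2 difference was 0.30 (SE 0.0764, limma adjusted p = 0.454). The same fit gave 0.36 for parental accelerated against high-to-low (adjusted p = 1), 0.24 for high-potential against high-to-low (adjusted p = 0.292) and -0.12 between the accelerated groups (adjusted p = 0.653).

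**Figure D1:**
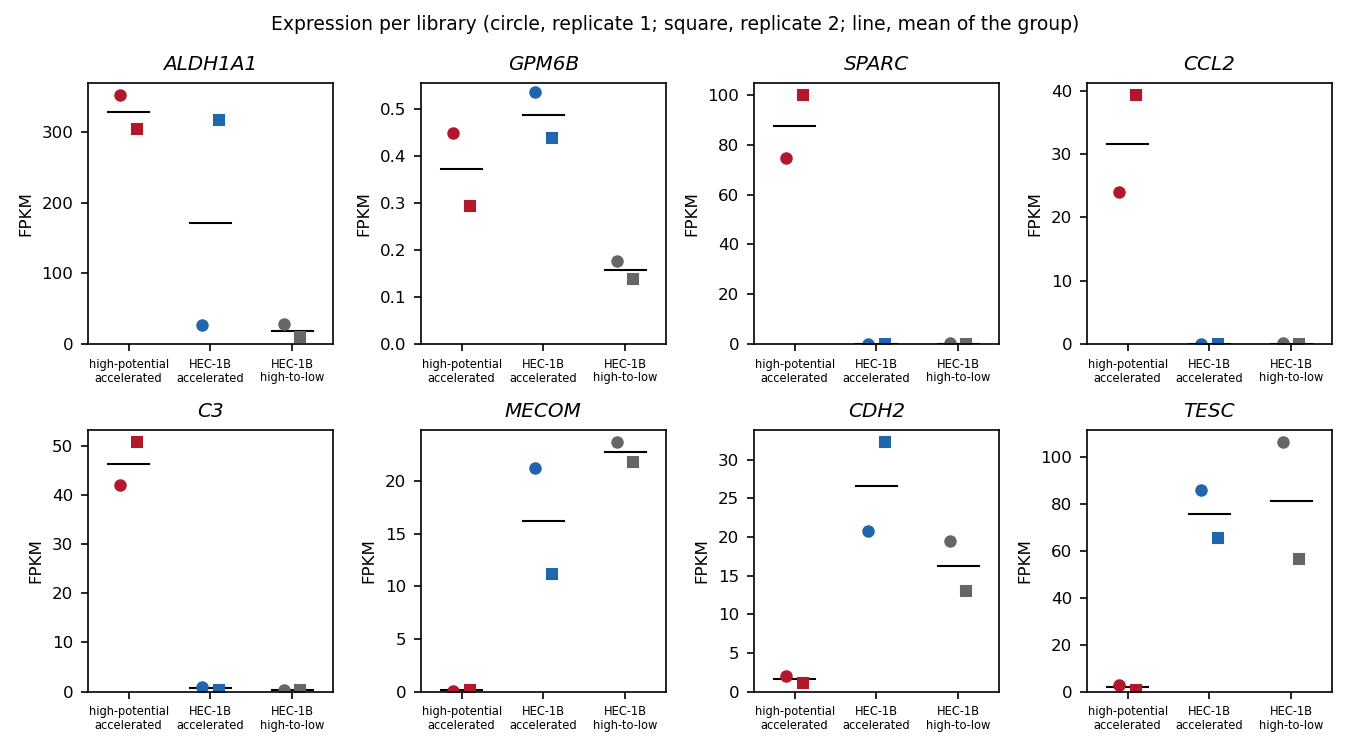
FPKM of 8 genes in each of the 6 libraries, with 1 panel per gene, groups along the horizontal axis, FPKM from 0 on the vertical axis, a circle for replicate 1, a square for replicate 2 and a line at the mean of the 2 libraries. ALDH1A1 is 26.7 FPKM in 1 parental accelerated library and 316.9 in the other, while SPARC, CCL2 and C3 are high, and MECOM, CDH2 and TESC low, in the high-potential libraries.

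SPARC, C3, CCL2 and BMP5 were higher in high-potential than in parental accelerated cells, where each stayed below 1 FPKM in both libraries, while IGFBP3 and TFPI2 were also expressed in parental accelerated cells, at lower levels. SPARC, a matricellular glycoprotein, averaged 87.4 FPKM (SD 17.8, n = 2) against 0.0433 in the parental accelerated libraries, a log2 difference of 6.39 (SE 0.258, limma adjusted p = 0.00036). IGFBP3, an insulin-like growth factor binding protein, was 206.4 and 388.9 against 4.71 and 17.3 FPKM (4.80, SE 0.572). The complement component C3 was 46.3 against 0.693 FPKM (4.82, SE 0.265). TFPI2, a secreted serine protease inhibitor, was 880.8 against 58.9 FPKM (3.95, SE 0.409). BMP5, a ligand of the bone morphogenetic protein family, was 12.1 against 0.0255 FPKM (3.65, SE 0.261). CCL2, a chemokine for monocytes, was 23.9 and 39.3 FPKM and is listed at 0 in both parental accelerated libraries, and IL8, a chemokine for neutrophils, was 22.0 against 0.523 FPKM (3.94, SE 0.42). Small RNA genes made up 7 of the calls. MIR4273 (1704 and 327.4 FPKM), SNORD83B (230.8 and 286.0), SNORD116-4 (146.6 and 181.8), SNORA66 (44.0 and 54.6) and SNORA18 (45.7 and 113.3) are listed at 0 in both parental accelerated libraries, and MIR568 and MIR659 are listed at 0 in both high-potential libraries.

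Among the genes lower in the high-potential cells, MECOM, a zinc finger transcription factor, was 0.112 FPKM (SD 0.0141, n = 2) against 16.1 in the parental accelerated libraries (log2 difference -3.88, SE 0.314, limma adjusted p = 0.0101). CDH2, the N-cadherin gene, was 1.57 against 26.6 FPKM (-3.41, SE 0.328). TESC, encoding the calcium-binding protein tescalcin, was 1.80 against 75.7 FPKM (-4.90, SE 0.49). VAV3, a guanine nucleotide exchange factor, was 2.35 against 45.1 FPKM (-3.71, SE 0.381). BEX2 (-4.27), TMEM47 (-3.90), FHL2 (-2.63), DBC1 (-2.55) and ACBD5 (-2.43) fell as well, and SLC25A43 is listed at 0 in both high-potential libraries and at 4.98 and 9.67 FPKM in the parental accelerated libraries. In all, 60 of 12135 genes passed between the accelerated groups, 35 higher and 25 lower in high-potential cells, and 1738 had an unadjusted p under 0.05 where chance gives 607 (1017 without high-potential replicate 2). With a term for the replicate number, which no label calls a pairing, 546 genes passed (186 higher and 360 lower). The count and the balance of directions thus depend on the model. Libraries of the groups did not overlap for 43.4% of genes, where chance gives 33.3%. Of the 17 protein-coding genes named here as passing, SPARC, C3, CCL2 and BMP5 (4) kept the call without any 1 library. The count was 25 and 14 without high-potential replicates 1 and 2, 21 and 22 without parental accelerated replicates 1 and 2, and 38 and 37 without high-to-low replicates 1 and 2.

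Inflammatory genes formed the clearest group. Of 18 tested members of the list of NF-kB targets and cytokines, 17 were higher in high-potential than in parental accelerated cells, with a median log2 difference of 1.17 (camera adjusted p = 4.94e-12; adjusted p = 0.658 with an estimated correlation). CCL2, IL8 and TNF passed over all genes tested (3), and 13 members passed adjusted over the list alone. TNF was 5.22 and 12.5 FPKM against 0.0669 and 0.0684. NFKBIA, the inhibitor that NF-kB itself induces, was 155.1 and 185.3 against 61.0 and 62.1 FPKM (limma adjusted p = 0.156), and LIF had the opposite sign (-0.14). Markers of leukocytes stayed at or below 1.79 FPKM, of endothelium at or below 0.92 and of fibroblasts at or below 0.414 in all 6 libraries. Of 16 markers of neurons and glia, TUBB3 reached 10.4 FPKM in parental accelerated replicate 2 and MBP 5.19 in high-to-low replicate 1, and the others stayed at or below 0.837 (SNAP25).

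**Figure D2:**
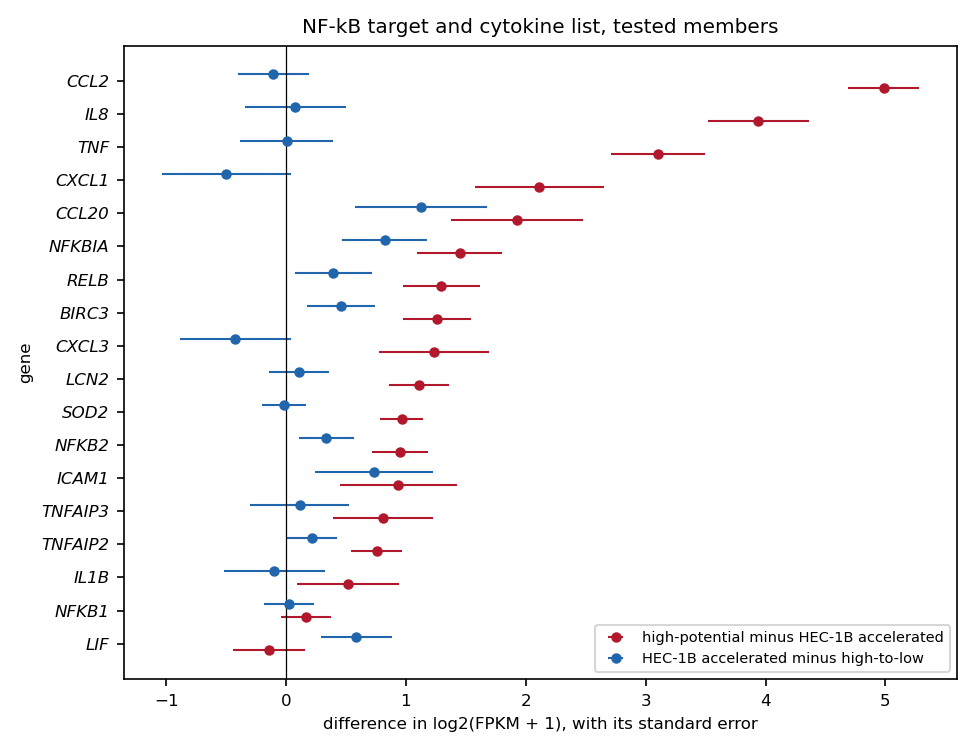
Difference in log2(FPKM + 1) for the 18 tested members of the NF-kB target and cytokine list, on the horizontal axis with 1 gene per line, for high-potential minus parental accelerated libraries (red) and parental accelerated minus high-to-low libraries (blue); points are limma estimates and bars their standard errors. In red 17 of 18 members are above 0, from 4.99 for CCL2 to -0.14 for LIF.

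Other lists were called between the accelerated groups with smaller shifts. In the retinoid list, 9 of 13 members were higher (median 0.21, camera adjusted p = 0.0403; adjusted p = 0.687 with an estimated correlation). STRA6, the receptor for retinol uptake, rose to 9.74 and 11.4 FPKM from at most 0.189 (log2 difference 3.40, SE 0.239, limma adjusted p = 0.00597). CYP26A1, which degrades retinoic acid, was 4.31 and 15.7 FPKM against 0.153 and 0.314 (limma adjusted p = 0.105), and RDH10, which makes retinaldehyde, was 163.7 and 127.8 FPKM against at most 43.2 (limma adjusted p = 0.137). In the list of TGF-beta and BMP targets, 11 of 15 were higher (median 0.43, camera adjusted p = 0.0126; adjusted p = 0.658 with an estimated correlation), and ID4 rose from 9.86 and 10.3 to 70.0 and 137.6 FPKM (3.16, SE 0.395, limma adjusted p = 0.0411). Cholesterol synthesis genes were higher in 16 of 22 cases (median 0.43, camera adjusted p = 0.00598; adjusted p = 0.687 with an estimated correlation) with no member passing over all genes. Genes of the ATF4 amino acid response were lower in 18 of 19 cases (median -0.52, camera adjusted p = 0.00598; adjusted p = 0.985 with an estimated correlation), and PHGDH, a serine synthesis enzyme, was 135.6 and 21.6 FPKM in the high-potential libraries. In the list of stemness markers 8 of 10 were lower (median -0.72, camera adjusted p = 0.0119; adjusted p = 0.687 with an estimated correlation). CD44 was 7.54 and 4.72 against 22.6 and 18.2 FPKM (limma adjusted p = 0.106), and CD24 was 215.5 FPKM in parental accelerated replicate 1 and 0.253 in replicate 2. L1CAM, a cell adhesion molecule, rose by 3.37 (SE 0.424, limma adjusted p = 0.0411); its list of adhesion and surface genes was not called (camera adjusted p = 0.451). Without high-potential replicate 2 the ATF4 median was -0.06 and the cholesterol median 0.20, and the calls of both, and of the retinoid and stemness lists, were lost. The stemness and TGF-beta calls were lost without parental accelerated replicate 1, and the retinoid, cholesterol and ATF4 calls without replicate 2.

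Against the high-to-low libraries, high-potential accelerated cells differed in many of the same genes. These groups differ in the high-potential label as well as in the transition, and no high-potential high-to-low group exists. The label and the transition therefore cannot be told apart in this comparison. The mean of the accelerated groups carries the same mix in part. SPARC was higher by 6.23 on the log2 scale (SE 0.258, limma adjusted p = 0.000595), IGFBP3 by 5.46, C3 by 5.12, CCL2 by 4.88, TFPI2 by 4.14 and IL8 by 4.02. Lower were TESC (-4.95), MECOM (-4.41), BEX2 (-4.07), VAV3 (-4.02), TMEM47 (-3.70), AFAP1L2 (-3.32), CDH2 (-2.74), SDC1 (-2.71), DBC1 (-2.70), FHL2 (-2.67) and DPYD (-2.58), and SLC25A43 is listed at 0 in the high-potential libraries. SDC1 encodes the proteoglycan syndecan-1 and DPYD the first enzyme of pyrimidine breakdown. MIR4273, SNORD83B, SNORD116-4, SNORA66, SNORA45 and SNAR-E, small RNA genes, are listed at 0 in both high-to-low libraries. In total 97 genes passed, 48 higher and 49 lower, 2233 had an unadjusted p under 0.05 (607 by chance; 1297 without high-potential replicate 2 and 1341 without high-to-low replicate 2), and 51.1% did not overlap (33.3% by chance). The count was 22 and 15 without high-potential replicates 1 and 2, and 21 and 13 without high-to-low replicates 1 and 2; C3, CCL2 and SPARC (3 of 18 coding genes named as passing) kept the call without any 1 library. With a term for the replicate number, which no label calls a pairing, 944 genes passed (301 higher and 643 lower), so the even split depends on the model. In the main fit, calls of this comparison and of the accelerated groups against each other overlapped in 54 genes, 31 higher and 23 lower in both. In 20 simulations of unchanged groups, which give almost no calls, the 97 and 60 genes of lowest p shared a mean of 16.6 genes in the same direction (13 to 24), from the shared libraries alone. Independent lists would share 0.14 and 0.1, and the 2 shared libraries cannot be split, so part of the excess may come from them.

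The NF-kB list was again the clearest group, with 18 of 18 members higher than in high-to-low libraries (median 1.45, camera adjusted p = 5.1e-13; adjusted p = 0.567 with an estimated correlation), 3 passing over all genes and 13 adjusted over the list alone. TGF-beta and BMP targets were higher in 12 of 15 cases (camera adjusted p = 0.0165; adjusted p = 0.567 with an estimated correlation) and retinoid genes in 10 of 13 (0.0171; adjusted p = 0.797 with an estimated correlation). Stemness markers were lower in 9 of 10 cases (camera adjusted p = 0.0171; adjusted p = 0.797 with an estimated correlation), and CD44, a hyaluronan receptor, fell by 2.27 (limma adjusted p = 0.044). Oxidative phosphorylation genes were lower in 19 of 28 cases (camera adjusted p = 0.0228; adjusted p = 0.797 with an estimated correlation), with UQCRC2 passing (limma adjusted p = 0.0438). ATF4 response genes were lower in 18 of 19 (median -0.46, camera adjusted p = 0.0228; adjusted p = 0.837 with an estimated correlation), but without high-potential replicate 2 the median was 0.02 (camera adjusted p = 0.982) and without high-to-low replicate 1 the call was lost. Cell cycle genes were lower in 25 of 30 (median -0.36, camera adjusted p = 0.0385; adjusted p = 0.923 with an estimated correlation), with no call and a median of -0.11 without high-potential replicate 1 and -0.08 without high-to-low replicate 2. The oxidative phosphorylation call was lost without either of these libraries and the retinoid call without the latter. Among the ALDH genes, ALDH1L2, a mitochondrial folate enzyme, fell by 1.95 (SE 0.285, limma adjusted p = 0.0496), and ALDH1A3 was 2.65 and 2.74 against 0.901 and 1.33 FPKM (limma adjusted p = 0.161). The ALDH list as a group was not called (camera adjusted p = 0.506).

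Between parental accelerated and high-to-low cells 2 genes passed. These, MIR568 and MIR659, are microRNA genes at 408.7 and 209.0 and at 171.3 and 175.2 FPKM in the accelerated libraries and listed at 0 in the others. Scaled to depth, the accelerated values were 380.2 and 190.1 for MIR568 and 159.4 and 159.3 for MIR659. No protein-coding gene passed limma's adjusted threshold, while 118 genes had an unadjusted p under 0.05, fewer than the 607 that chance gives. That number rested on single libraries: it was 808 without parental accelerated replicate 1, 289 without high-to-low replicate 1 and 51 without high-to-low replicate 2. Libraries did not overlap for 24.1% of genes, against 33.3% by chance. Coding genes named without passing were higher for PLA2G7 (1.46), ANKRD36 (1.06) and PAQR6 (0.99) and lower for IL1R2 (-2.01), CD70 (-1.64), CGREF1 (-1.43), AFAP1L2 (-1.27), AK5 (-1.21), TM4SF4 (-1.18), RAC2 (-1.17) and BEX5 (-1.16). Each has a limma adjusted p of 1. The count without 1 library lay between 4 and 7.

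List tests called 7 of 28 lists in that comparison. Interferon response genes were lower in 27 of 28 cases (median -0.34, camera adjusted p = 6.22e-05; adjusted p = 0.731 with an estimated correlation), among them PSMB9 at 83.2 and 16.8 against 82.3 and 89.1 FPKM and IFI6 at 33.3 and 15.6 against 40.4 and 37.1. Ribosomal protein genes were lower in 28 of 30 cases (camera adjusted p = 0.000169), cholesterol synthesis genes in 19 of 22 (0.000866), oxidative phosphorylation genes in 25 of 28 (0.00324) and housekeeping genes in 12 of 15 (0.0488). NRF2 targets were higher in 18 of 23 cases (camera adjusted p = 0.00252) and NF-kB genes in 13 of 18 (0.0154). With an estimated correlation each of these had an adjusted p of 0.731, and 0 members passed over all genes. The lists called lower also depended on scaling: 5 in the main fit, 2 with quantile normalization and 7 with median ratio scaling. Without parental accelerated replicate 2 the interferon median was 0.01 and the NRF2 median -0.04, so those shifts rested on 1 library. Without high-to-low replicate 2 the calls of the other 5 lists and of the NRF2 list were lost, and without parental accelerated replicate 1 those of the NF-kB and oxidative phosphorylation lists. The housekeeping call was lost without any 1 library other than high-to-low replicate 1.

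Averaged over the accelerated groups, 8 genes passed against high-to-low: 6 small RNA genes, SPARC and C3, the latter pair from the high-potential libraries. SNORA45, the only one that separated all 4 accelerated libraries, was 47.5, 58.9, 102.1 and 26.1 FPKM and listed at 0 in the high-to-low libraries (limma adjusted p = 0.029). Named without passing were the cytokine IL32 (2.28, limma adjusted p = 0.0639), CCL20 (2.09), C8orf4 (2.05), the sulfatase SULF2 (1.76), C12orf39 (1.69), ENPP5 (1.66) and NFKBIA (1.55). Lower without passing were KCNIP1 (-3.54), NUPR1 (-3.25), MECOM (-2.47), AFAP1L2 (-2.30), OLFML1 (-2.08), the hyaluronan synthase HAS3 (-1.99), LEMD1 (-1.74), IL1R2 (-1.71), SDC1 (-1.70), CD44 (-1.46) and the collagen-modifying PLOD2 (-1.42). At an unadjusted p under 0.05 there were 1122 genes, where chance gives 607, but the excess was lost without high-to-low replicate 2. That fit holds 1 high-to-low library, so lost power cannot be told apart from an excess that rested on the library left out. Of all genes, 13% did not overlap (13.3% by chance). The count was 15 without parental accelerated replicate 1 and 3 without high-to-low replicate 1. NF-kB genes were higher in 18 of 18 cases (median 0.74, camera adjusted p = 1.33e-12; adjusted p = 0.62 with an estimated correlation), 12 of them adjusted over the list alone and 0 over all genes. Also called were higher retinoid (camera adjusted p = 0.011) and TGF-beta and BMP lists (0.0161) and lower oxidative phosphorylation (0.00531), ribosomal protein (0.00531), interferon (0.00641), stemness (0.0284) and cell cycle (0.0345) lists. With an estimated correlation the interferon list had an adjusted p of 0.816, the cell cycle list 0.874 and the other 5 lists 0.701. Against high-to-low, the NF-kB median was 1.45 in high-potential and 0.11 in parental accelerated cells. The retinoid medians were 0.46 and 0.12, and those of TGF-beta and BMP targets 0.66 and 0.007. Stemness gave -0.82 and -0.12, cell cycle -0.36 and -0.11, and oxidative phosphorylation -0.26 and -0.15. Ribosomal protein (-0.17 and -0.15) and interferon genes (-0.33 and -0.34) were alike in both. The higher lists came mainly from the high-potential libraries. Without high-to-low replicate 2 the cell cycle median was 0.04, and the calls of the retinoid, oxidative phosphorylation, ribosomal protein and stemness lists were lost as well. Without parental accelerated replicate 1 the retinoid, oxidative phosphorylation and cell cycle calls were lost, and without replicate 2 the interferon call. The cell cycle call was also lost without high-potential replicate 1, the stemness call without high-potential replicate 2 and the TGF-beta call without high-to-low replicate 1, while the NF-kB call held without any 1 library.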

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

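The tests on labels, mixing and small RNA were chosen after the result was seen; those on batch, copy number and GC content were written before. Over the 4 accelerated libraries, 26 named genes were checked for a library apart from the rest and 5 met the criterion, where chance gives 1.3. That 1.3 holds for libraries of 1 group and genes not chosen by their values. Here the libraries come from both accelerated groups and most genes were chosen for their differences, so 5 against 1.3 does not show an excess.

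ALDH1A1 was 1 of the 5: in parental accelerated replicate 1 its gap to the next library took 0.85 of the range. An exchange with a high-to-low library would not explain the low value, since the high-to-low libraries reach 28.36 FPKM and no more. Those values cannot show whether labels were exchanged, because 26.67 FPKM in this library is close to 28.36 in high-to-low replicate 1. Mixing of high-potential cells into parental accelerated replicate 2 was also considered, since its ALDH1A1 was 96.6% of the high-potential mean. The median of SPARC, CCL2, C3, BMP5 and STRA6 there was 0% of their high-potential means. These genes were chosen as low in the parental accelerated libraries, this one included, so a low median was built in and the test cannot decide. The values show only that cells with the SPARC and CCL2 levels of the high-potential libraries were not seen there, as both are listed at 0. A wrong label on replicate 1 alone stays open: it correlates with high-to-low replicate 1 at 0.9641 and with its own group at 0.9324, but the other parental accelerated library also lies closer to high-to-low libraries. Variation between cultures in how far the transition had gone is a biological explanation that was not tested.

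The remaining library gaps are given as values. SNAR-E, at 114.4, 1041, 41.0 and 83.9 FPKM, had a gap of 0.927 of its range. C12orf39 had 0.835, with 26.7 FPKM in high-potential replicate 1. KCNIP1 had 0.954, with 52.3 FPKM in parental accelerated replicate 1 and at most 2.73 in the other accelerated libraries. OLFML1 had 0.86, with 44.2 FPKM in parental accelerated replicate 1 and 9.57 in replicate 2.

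Small RNA genes were prominent among the calls. Whether they rest on 1 to 3 fragments was tested through value ratios: 75% of pairs (9 of 12) matched ratios of whole fragment numbers within 3%, against 18% (46 of 256) in other called genes. That is below the 80% set for the test, so for the genes as a set counting noise cannot be told apart from a difference. Gene by gene, values scaled to depth say more. Within 3%, they were the same for SNORD83B (230.8 and 230.7) and SNORD116-4 (146.6 in both). The same held for SNORA66 (44.04 in both) and MIR659 (159.4 and 159.3). MIR568 (380.2 and 190.1) stood near a ratio of small whole numbers. So did SNORA18 (45.68 and 91.37 in high-potential, 68.52 and 22.84 in high-to-low libraries). SNORA45 did too (47.5 in both high-potential, 95.01 and 23.75 in parental accelerated libraries). A few fragments would give such values, so the calls of these genes may rest on counting noise.

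The 60 genes called between the accelerated groups are also those whose difference from the high-to-low libraries differed between high-potential and parental accelerated cells. That is the same result and not a further one, since the shared high-to-low libraries cancel. A batch term from the start of the numbers that end the descriptions kept 100% of the 24 named genes at an unadjusted p under 0.05, but each accelerated group holds 1 library of either start, so the design fixes the fold changes and that test decides nothing. Means over runs of 50 neighbouring genes spread 3.2 times as widely as in shuffled order, against 2.63 for parental accelerated against high-to-low. A copy number difference would give such a spread, but the intervals, 2.79 to 3.58 and 2.29 to 2.88, overlap, and replicates of 1 group gave 2.19 (parental accelerated), 1.63 (high-potential) and 1.23 (high-to-low). GC content is argued against, since the value was 3.19 with its trend removed, while copy number, neighbouring genes regulated together, and the cell state that the labels name, stay open, the last pair untested.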

How the results depend on the processing

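Of the alternatives, 19 were planned; leaving out small RNA genes was chosen after seeing the data. Gene counts in the order mean of accelerated against high-to-low, high-potential against high-to-low, high-potential against parental accelerated, and parental accelerated against high-to-low were 8, 97, 60 and 2. Pseudocount 0.1 gave 54, 31 and 4 in the last 3; no filter gave 3, 39 and 38 in the first 3; a mean of at least 3 FPKM gave 63 and 25 in the middle pair. Fitting only the groups compared gave 39 and 7 in the last pair. The batch term gave 15, 54, 105 and 7, and the 4 libraries whose description numbers share the earlier start gave, alone, 16, 12, 11 and 13. Those 4 hold 1 library of each accelerated group, so the accelerated groups are compared as 1 library against 1, and replicate spread comes from the 2 high-to-low libraries alone. Without small RNA genes the counts were 2, 164 and 0 for the first, second and last; the 0, from limma, stands beside 118 genes at an unadjusted p under 0.05 in the full fit. Leaving out 1 library gave 3 to 15, 13 to 115, 14 to 38 and 4 to 7. In these fits a lone library is assumed to vary like the other groups. The causes were not tested, except that fewer libraries or genes entered some fits.

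The replicate numbers share v1 and v2 but no label says that they pair samples. With the replicate block the counts were 17 (12 higher, 5 lower), 944 (301 higher, 643 lower) and 546 (186 higher, 360 lower) in the first 3 comparisons and 2 in the last, where 380 genes had an unadjusted p under 0.05. The replicate 1 minus 2 differences correlated between groups at 0.187, 0.158 and 0.281, and the component with 23.1% of the variance separated the numbers, a hint from the data and not the design.

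With an estimated correlation 0 lists were called in each comparison, against 8, 7, 6 and 7. Quantile normalization gave 5 for the first and 4 for the last, and the earlier-start libraries alone 5 for the first and 3 for high-potential against parental accelerated. Leaving out 1 library gave 4 to 9, 4 to 8, 4 to 9 and 2 to 11. List medians changed sign for the ATF4 list in 2 comparisons, with medians from -1.18 to 0.0182 over libraries left out (the latter without high-potential replicate 2) against high-to-low and 0.174 in the earlier-start libraries alone, 1 against 1, between the accelerated groups. The same held for cell cycle in the mean of accelerated (-0.531 to 0.0446, the latter without high-to-low replicate 2) and for interferon in parental accelerated against high-to-low (-0.529 to 0.00616, the latter without parental accelerated replicate 2). Without that library the NRF2 median in this comparison also changed sign, to -0.0379, while camera's direction stayed higher and the call was lost. Among named genes, 364 of 469 alternatives for high-potential against high-to-low and 367 of 468 against parental accelerated left the side of the threshold as it was, with 0 reversed. The naming rule asks for libraries that do not overlap, so leaving out a library could not reverse such a gene. The 0 is therefore no measure of stability. Depth limits genes near 0.1 FPKM.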

Other observations

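The copy number and GC tests were written before their results were seen; the correlation across runs of genes was chosen afterwards. THY1, CD24 and CLDN4, chosen after their values were seen, differed between the parental accelerated replicates. THY1 was 297.1 FPKM in replicate 1 and 8.04 in replicate 2, CD24 215.5 and 0.253, and CLDN4 52.5 and 3.47, while the high-to-low libraries held THY1 at 313.9 and 272.5, CD24 at 206.5 and 29.8 and CLDN4 at 43.6 and 10.1. Epithelial genes were lower in 8 of 12 cases in high-potential than in parental accelerated cells (camera adjusted p = 0.096), with KRT8 at 49.4 and 47.1 against 96.9 and 104.1 FPKM.

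Along the gene order, some stretches were lower in high-potential cells almost throughout. In the run of 50 genes from XPC to CLASP2, 50 were lower than in parental accelerated cells, with a mean log2 difference of -0.87. The run from TRMT2B to SLC25A5 was similar (-0.92, 46 of 50 lower). Other runs went the opposite way, as from SEC23A to CNIH (0.297, 7 of 50 lower). That last run was not particular to high-potential cells. Relative to the mean of all libraries, it stood at 0.21 and 0.28 in high-potential and at -0.24 and 0.14 in parental accelerated replicates 1 and 2. The high-to-low libraries were at -0.22 and -0.17. All the runs named are examples out of 224 runs. A loss of copies in the high-potential cells may underlie the lower runs, given the spread of 3.2 times that of shuffled order. However, no DNA was measured, and the parental accelerated replicates alone gave 2.19. That 2.19 is not a plain noise level, since the replicate difference went in part with the high-potential pattern, as given next. Across the 224 runs, the difference of parental accelerated replicate 2 from replicate 1 correlated with that of high-potential cells from high-to-low cells (Pearson r = 0.404, Spearman rho = 0.321, permutation p = 1e-04, the smallest 10000 shuffles give). These differences share no library, but they share a contrast of description numbers. Parental accelerated replicate 2 and high-potential replicate 2 have numbers of the later start, and the other libraries of the earlier. A batch behind these numbers, if they mark one, could add to the correlation, which was not tested. Runs are not independent replicates.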
